A study of Mus musculus with 6 samples.

How the data were processed

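Total RNA from the liver of 6 male mice was measured on Affymetrix whole-transcript arrays, 1 array per mouse. The mice belonged to the substrains Balb/c and Balb/cBy, with 3 arrays per substrain. Per the labels' protocols, they were fed a diet with 58% of energy as fat for 12 weeks from 8 weeks of age, RNA was extracted with Trizol, and biotinylated single-stranded cDNA was made from 500 ng of total RNA with the GeneChip WT PLUS kit. Samples were grouped by the substrain in their labels.

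The deposited values are on the log2 scale, 1 per probe set and array. Per the submitters' processing notes they were made with RMA, a method that corrects background, quantile-normalizes the arrays and summarizes the probes of each probe set. The software, its version and the genome build behind the probe sets were not given in the sources used here. The values ranged from 3.31 to 14.84, and the median over the tested probe sets lay between 7.98 and 8.03 on every array. No background or detection measure was used, since the table holds summarized values alone. As a stand-in added after the data were seen, 8.02, the 95th percentile of the mean log2 values of 1105 olfactory receptor genes, was taken as the level below which a gene may not be told from background. RMA pulls values at the low end together, so differences of dim genes are understated.

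The table holds 41345 probe sets. The platform annotation lists 25335 of them: 23521 with 1 gene symbol, covering 22180 genes, and 1814 with several symbols. The other 16010 are unlisted in it and carry no name here. The main test used the 23521 probe sets with 1 symbol. The 17824 others were tested by their IDs only in the alternative over every probe set, in which 0 of them passed. Of the tested probe sets, 107 had values identical to another on every array, 15 of them copies of the predicted gene Gm26504. Neighbouring genes were read from a RefSeq gene table of the assembly GRCm38.p6, used only for names and order, in which 99.1% of the genes were found.

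The groups were compared with limma 3.58.1 in R 4.3.3. A linear model with the group as its single term was fitted to every probe set, followed by empirical Bayes moderation. Differences are given as Balb/cBy minus Balb/c on the log2 scale with the moderated standard error (SE). Tests were two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Where a gene has several probe sets, the one with the highest mean is reported. A comparison of 3 with 3 arrays cannot reach a permutation p under 0.1, so the tests of single genes rest on limma's model. The number of arrays limits the precision. Changes planted in simulated arrays of the same size and spread were recovered in 31.3% of cases at 1.5-fold, 86.6% at 2-fold and 95.5% at 4-fold. There were 7 false calls beside 200 true changes. All changes were planted together and noise was drawn independently for each probe set, so these shares may not hold on the real arrays. There Creld2, at 2.33-fold, did not pass.

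Of 37 gene lists for liver metabolism, stress, inflammation and cell types, holding 719 genes, 36 had 5 or more measured genes and were tested with limma's camera at its preset correlation between genes of 0.01. The alternatives were camera with the correlation estimated from the arrays, and fry, which asks whether the genes of a list move on balance one way. Member genes were also adjusted over the list alone. That adjustment does not correct for the number of lists, so some lists may hold a passing gene by chance. List genes that share a probe set with another symbol or carry no probe set with 1 symbol were left out of the list tests. On simulated arrays, a list of genes shifted by 0.3 was called, as was 1 unshifted list. The simulated genes varied independently, while the correlation estimated on the real arrays was 0.60 for cholesterol synthesis. The simulation therefore does not give camera's rate of false calls on the real lists.

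The groups, the test, the gene lists, the rule for named genes and the alternatives below except the last were fixed before the data were examined. The rule names the 5 measured genes of a list of genes known to differ between mouse substrains, the 20 genes with the smallest p where fewer than 20 passed, leaving out predicted genes and those of olfactory, vomeronasal, microRNA and snoRNA names, and up to 4 members of each list with the smallest p. It was applied with 4 members for lists called by camera and 2 for the rest, a narrowing chosen after the data were seen, which gave 115 genes. Another 15 genes were named after their values were seen: Sdf2l1, Asns, Atf4, Saa3, a pair of Igkv segments and the genes of neighbouring pairs in the closing section. H2-Q5, Sdc1, Prdm1, Zfand3 and 1700097N02Rik were likewise named after their values were seen.

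The alternatives were limma with a mean trend and robust moderation, no moderation, array weights, the replicate number as a block, renewed quantile normalization, median centring, a filter that kept the brighter probe sets, every probe set, a single or averaged probe set per gene, an added minimum of 1.5-fold, and leaving out each array in turn. Leaving out both arrays with the lowest weights was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.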

Results

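Liver gene expression was compared between Balb/c mice, which the series calls wild type, and Balb/cBy mice, a closely related substrain that the series calls KD. Each group held 3 male mice at 20 weeks of age, after 12 weeks on a high-fat diet. The labels call the 3 arrays of a group biological replicates, so the p-values of single genes measure the spread between these animals. Camera's p-values at the preset correlation weigh a list's genes against the other genes and do not measure that spread. The 6 arrays were alike in signal: Pearson correlations across genes ran from 0.977 to 0.990 within groups and from 0.977 to 0.991 between them. The first principal component held 34.9% of the variance and did not part the substrains. It set Balb/c replicates 2 and 3 and Balb/cBy replicate 1 on the positive side and the other 3 arrays on the negative side. The array weights of limma were lowest for Balb/cBy replicate 1, at 0.471, and Balb/c replicate 3, at 0.635, and highest for Balb/cBy replicate 3, at 2.47.

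Acads, which encodes short-chain acyl-CoA dehydrogenase of mitochondrial fatty acid oxidation, was examined first. The labels name no gene for the term KD, but the BALB/cBy substrain is known to carry a spontaneous deletion in this gene. The log2 level of Acads (probe set 17451649) was 11.43 ± 0.13 (SD, n = 3) in Balb/c and 10.77 ± 0.17 (SD, n = 3) in Balb/cBy. The difference was -0.65 ± 0.12 (SE, 95% interval -0.93 to -0.38), a level 0.636 times that of Balb/c. The Balb/c arrays read 11.53, 11.46 and 11.28, and the Balb/cBy arrays 10.60, 10.79 and 10.93, so the groups did not overlap. Its adjusted p was 0.319 over all genes and 0.00265 adjusted over the list alone. Where the probes lie relative to the deletion was not given in the sources used here, so the level alone does not check the labels. The other 4 measured genes of the substrain list did not pass either way. Zhx2, a regulator of fetal liver genes, differed by 0.13 ± 0.10 (SE), and its target Afp by 0.08 ± 0.10 (SE). Gpc3 differed by -0.09 ± 0.11 (SE) and Nnt, a mitochondrial transhydrogenase, by -0.10 ± 0.09 (SE). Camera did not call the list as a whole (median -0.09, adjusted p = 0.199). Afp and Gpc3 lay under 8.02, the level of olfactory receptor genes, in both groups.

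Among single genes, the smallest p-values belonged to genes of varied function, most of them higher in Balb/cBy. Mid1, a ubiquitin ligase bound to microtubules, came first, followed by Creld2, a protein of the endoplasmic reticulum (ER), Ubtd1, Oas1g and Obp2a. None of the 23521 probe sets passed limma's adjusted p of 0.05 with all arrays weighted alike; the smallest adjusted p was 0.177. At an unadjusted p under 0.05 there were 899 probe sets, 621 higher and 278 lower in Balb/cBy, where chance alone gives 1176. Array weights in limma called 31 probe sets of 17 genes, 29 higher and 2 lower. Among the 29, 15 were copies of the predicted gene Gm26504 with identical values. Leaving out 1 array at a time called 2 without Balb/c replicate 3, 4 without Balb/cBy replicate 1 and 0 otherwise, and 16 were called without the 2 arrays of lowest weight. The other settings tried called 0. The groups did not overlap in 1736 genes, or 7.83%, against 10% by chance.

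Of the 20 named genes with the smallest p, 17 were higher and 3 lower in Balb/cBy, and in each of them the groups did not overlap. Picking genes by small p favours such separation, so it adds no separate evidence. The largest difference was that of Obp2a, an odorant-binding lipocalin: its log2 level was 9.02 ± 1.23 (SD, n = 3) in Balb/c and 13.01 ± 0.25 (SD, n = 3) in Balb/cBy, 15.9 times higher, with an adjusted p of 0.177. Balb/c replicate 3 stood apart at 10.40, against 8.08 and 8.58 on the other Balb/c arrays. Without it Obp2a passed at 4.69 (adjusted p = 0.000464), as did the interferon-induced Oas1g at 1.89 (adjusted p = 0.0179). Over the settings run for single genes the adjusted p of Obp2a ran from 0.000464 to 0.999 and that of Oas1g from 0.00775 to 0.999, the highest values being those of limma without moderation. With all arrays Oas1g differed by 1.65 ± 0.21 (SE), though its mean lay under the olfactory receptor level of 8.02 in both groups. Bmyc, a Myc family member, differed by 0.82 ± 0.11 (SE), Mid1 by 1.13 ± 0.13 (SE), and Ubtd1 by 0.93 ± 0.12 (SE). The receptor genes Il1r1, for interleukin 1, and Osmr, for oncostatin M, differed by 1.19 ± 0.16 and 0.76 ± 0.11 (SE). Kyat3, a kynurenine aminotransferase, differed by 1.01 ± 0.17 (SE), and Snx32, a sorting nexin, by 0.59 ± 0.09 (SE) from a Balb/c mean under the olfactory receptor level. The genes lower in Balb/cBy were Macroh2a1, a histone variant, at -0.75 ± 0.12 (SE), Inf2, a formin, at -0.84 ± 0.13 (SE), and Slc17a8, a vesicular glutamate transporter, at -0.80 ± 0.14 (SE). Array weights called Mid1, Ubtd1, Oas1g, Obp2a, Bmyc, Snx32, Macroh2a1 and Inf2 among others.

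**Figure D1:**
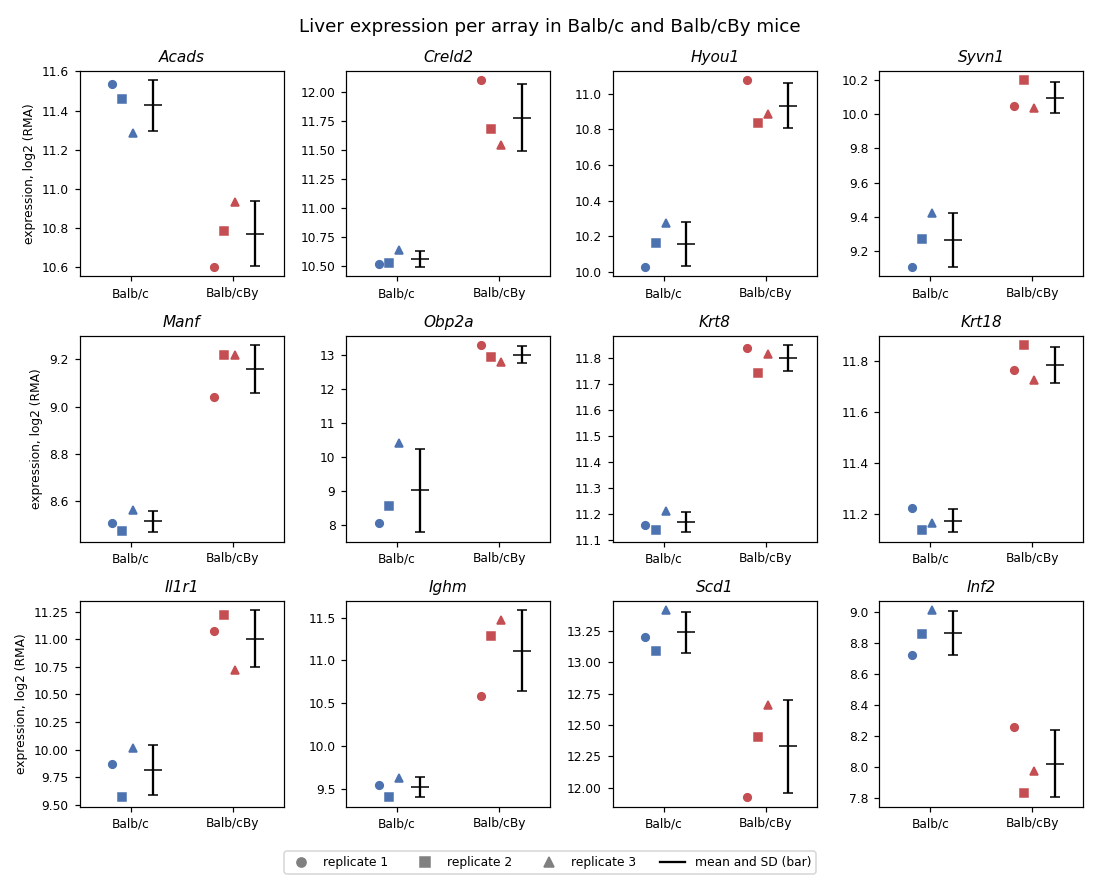
Log2 RMA expression of 12 genes on each array (vertical axes, scaled per gene) in Balb/c and Balb/cBy liver. Symbols are the 3 replicates of each group and the bars the mean and SD. The groups did not overlap in any of the 12 genes, most of which were named for their small p. Acads, Scd1 and Inf2 were lower in Balb/cBy.

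Genes of the ER stress and amino acid response, which serve protein folding, degradation from the ER and amino acid supply, were higher in Balb/cBy. Of 23 measured members, 20 were higher and 3 lower, with a median difference of 0.27 and a mean of 0.32. The mean of the list was 9.83, 9.80 and 9.85 on the Balb/c arrays and 10.15, 10.19 and 10.09 on the Balb/cBy arrays. Over all genes 0 members passed, and adjusted over the list alone 7 rose and 0 fell. These were Creld2 (1.22 ± 0.15 SE), an ER disulfide isomerase, the ER chaperones Hyou1 (0.78 ± 0.11 SE), Hspa5 (0.58 ± 0.12 SE) and Sdf2l1 (0.85 ± 0.23 SE), and Sel1l (0.46 ± 0.09 SE), an adaptor of ER-associated degradation. Asns, asparagine synthetase, followed at 0.39 ± 0.12 (SE), and Atf4, a transcription factor of the response, at 0.34 ± 0.11 (SE). Off the list, Syvn1, the ubiquitin ligase of ER-associated degradation, differed by 0.83 ± 0.11 (SE) and Manf, a secreted ER stress protein, by 0.65 ± 0.09 (SE). Both were named for being among the 20 smallest p-values, so they are no separate support for the list. Array weights in limma called Creld2, Hyou1, Syvn1 and Manf. Whichever array was left out, Creld2, Hyou1, Sel1l and Hspa5 passed over the list alone. Without 1 array Sdf2l1 passed in 2 of 6 fits (0.63 to 1.07), Asns in 1 (0.31 to 0.50) and Atf4 in 1 (0.25 to 0.40). Asns passed only without Balb/cBy replicate 3, Atf4 only without Balb/cBy replicate 1, and Sdf2l1 only without Balb/c replicate 2 or Balb/cBy replicate 2. Camera called the list (adjusted p = 3.4e-11) and kept the call whichever array was left out, with means from 0.29 to 0.35. Its adjusted p was 0.132 with an estimated correlation, above the threshold but the smallest of any list, and 0.0284 by fry; over the settings run for lists it ran from 3.6e-12 to 0.132.

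Camera called lists of fatty acid oxidation and amino acid breakdown lower in Balb/cBy by small amounts. No call held with an estimated correlation, where the adjusted p was 0.552 for peroxisomal β-oxidation and PPARα targets, 0.834 for mitochondrial β-oxidation and 0.868 for amino acid breakdown. Without the 2 arrays of lowest weight none was called, and mitochondrial β-oxidation (mean 0.0096) and amino acid breakdown (0.030) turned sign. There the means were -0.10 for peroxisomal β-oxidation and -0.080 for PPARα targets. Of 18 measured genes of peroxisomal β-oxidation, 15 were lower (median -0.18), and 1, Acaa1b, a peroxisomal thiolase, fell when adjusted over the list alone, at -0.87 ± 0.20 (SE). It passed there only without Balb/cBy replicate 1 (-0.61) or Balb/cBy replicate 2 (-1.0045) when single arrays were left out. Abcd3, a peroxisomal membrane transporter, differed by -0.35 ± 0.13 (SE) and Hsd17b4, the multifunctional enzyme of the pathway, by -0.20 ± 0.09 (SE). Of 22 targets of the lipid-sensing receptor PPARα, 15 were lower (median -0.17) and 0 passed over the list alone; Acot1 differed by -0.42 ± 0.14 (SE) and Fgf21 by -0.21 ± 0.10 (SE). Of 23 genes of mitochondrial β-oxidation, which the list keeps apart from Acads, 20 were lower (median -0.09) and 0 passed; Hadh differed by -0.14 ± 0.09 (SE) and Etfa by -0.24 ± 0.16 (SE). Of 18 genes that break down branched-chain amino acids and propionate, 15 were lower (median -0.06) and 0 passed, among them Hibch at -0.43 ± 0.17 (SE). Camera called the 4 lists, with adjusted p = 0.000197 for peroxisomal β-oxidation, 0.00203 for PPARα targets, 0.00741 for mitochondrial β-oxidation and 0.0477 for amino acid breakdown. The differences leaned on Balb/cBy replicate 1: without it the means of the lists were -0.12, -0.057, -0.015 and -0.020 in the same order, against -0.19, -0.13, -0.10 and -0.085 with all arrays, and no call was left. Leaving out Balb/c replicate 1 ended the calls of PPARα targets (mean -0.073), mitochondrial β-oxidation (-0.082) and amino acid breakdown (-0.066). Leaving out Balb/c replicate 3 ended those of mitochondrial β-oxidation (-0.075) and amino acid breakdown (-0.035). The means grew without Balb/cBy replicate 2 for PPARα targets (-0.22) and mitochondrial β-oxidation (-0.16), and without Balb/c replicate 2 for amino acid breakdown (-0.15). They also grew with renewed quantile normalization for mitochondrial β-oxidation (-0.15) and amino acid breakdown (-0.14). The call of amino acid breakdown was also lost with median centring (adjusted p = 0.0715) and with averaged probe sets (adjusted p = 0.0582), its range over the settings run for lists being 0.000213 to 0.949.

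Lipid synthesis and storage showed single genes rather than whole lists. Scd1, the stearoyl-CoA desaturase, read 13.24 ± 0.16 (SD, n = 3) in Balb/c and 12.33 ± 0.37 (SD, n = 3) in Balb/cBy, a difference of -0.91 ± 0.18 (SE). It was the 1 of 23 lipogenesis genes that fell when adjusted over the list alone (adjusted p = 0.0254), and its adjusted p was 0.470 over all genes. Over the list alone it was short of the threshold without Balb/c replicate 1 (-0.93), Balb/c replicate 2 (-0.98) or Balb/cBy replicate 2 (-0.95). Elovl5, a fatty acid elongase, differed by -0.41 ± 0.19 (SE). Apoa4, an apolipoprotein on the list of lipid droplets and triglyceride storage, differed by 0.70 ± 0.11 (SE) and was the 1 of 22 genes that rose over the list alone, whichever array was left out. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 1.24 ± 0.39 (SE), with overlapping groups, and Nr0b2, a repressor of bile acid synthesis, by -0.44 ± 0.16 (SE); neither passed. Camera called none of these lists: the adjusted p was 0.0908 for lipogenesis (median -0.04), 0.555 for lipid storage (0.04), 0.424 for bile acids (-0.09) and 0.0738 for cholesterol synthesis (0.08). Leaving out 1 array gave calls to all 4. Lipogenesis was called lower without Balb/c replicate 2 (mean -0.13), Balb/c replicate 3 (-0.15), Balb/cBy replicate 2 (-0.18) or Balb/cBy replicate 3 (-0.14), with renewed quantile normalization (-0.14) and with the brighter probe sets alone (-0.099). Cholesterol synthesis was called higher without Balb/c replicate 1 (0.20) or Balb/cBy replicate 1 (0.27) and with the replicate block (0.11). Bile acid genes were called lower without Balb/c replicate 2 (-0.13) but higher without the 2 arrays of lowest weight (0.16). Lipid storage was called higher without Balb/cBy replicate 1 (0.14), and cholesterol synthesis also without the 2 arrays of lowest weight (0.19).

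The acute phase, glucocorticoid response and interferon response lists were called higher in Balb/cBy by camera, and the calls of acute phase and glucocorticoid genes ended without single arrays. Of 24 acute phase genes, 21 were higher (median 0.20, adjusted p = 6.99e-05, and 0.552 with an estimated correlation). Steap4, a metalloreductase induced by cytokines, rose by 1.09 ± 0.22 (SE) over the list alone. It did not pass without Balb/c replicate 1 (1.04), Balb/cBy replicate 1 (0.97) or Balb/cBy replicate 2 (0.95). Mt1, a metallothionein, differed by 0.88 ± 0.33 (SE). Saa3, a serum amyloid, went the other way at -1.41 ± 1.07 (SE) with a wide spread, in which Balb/c replicate 3 read 9.37 beside 13.88 and 13.73 on the other Balb/c arrays. Without that array the mean of the acute phase list was 0.00063, against 0.24 with all arrays, and the call was lost. The call was also lost without Balb/cBy replicate 1 (0.13), and the mean was 0.40 without Balb/c replicate 2. Without the 2 arrays of lowest weight the mean turned to -0.11, not called, and Saa3 passed as lower at -2.71 (adjusted p = 0.0491). Glucocorticoid response genes behaved likewise: 13 of 16 were higher (median 0.27, adjusted p = 0.011, and 0.552 with an estimated correlation). Their mean was 0.046 in place of 0.27, not called, without Balb/c replicate 3. The call was also lost without Balb/cBy replicate 3 (mean 0.28), without the 2 arrays of lowest weight (0.10) and with the brighter probe sets alone (adjusted p = 0.0796; range over the settings run for lists 0.000314 to 0.81). Of its genes 0 passed over the list alone. Of 27 interferon response genes, 22 were higher (median 0.11, adjusted p = 0.000475, and 0.552 with an estimated correlation), among them Stat2 at 0.41 ± 0.10 and Usp18 at 0.66 ± 0.19 (SE). Cxcl9, an interferon-induced chemokine, was lower at -1.25 ± 0.39 (SE). None of the 27 passed over the list alone, and the mean was 0.031 in place of 0.10 without Balb/cBy replicate 2, where the list was still called. The mean was 0.17, also called, without the 2 arrays of lowest weight.

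Camera also called lists of several other cell types, with small differences and no call held with an estimated correlation. Stellate cell and matrix genes were called higher (21 of 25, median 0.15, adjusted p = 0.000238, and 0.686 with an estimated correlation), and Lum, a matrix proteoglycan, rose over the list alone at 0.53 ± 0.12 (SE) from a Balb/c mean of 7.91, under the olfactory receptor level. When single arrays were left out it passed only without Balb/c replicate 1 (0.64) or Balb/cBy replicate 1 (0.59). Dcn, decorin, differed by 0.48 ± 0.14 (SE). Neutrophil markers (10 of 14 higher, median 0.11, adjusted p = 0.00891, and 0.552 with an estimated correlation) included Retnlg at 0.40 ± 0.11 (SE), with both group means under the olfactory receptor level. Kupffer cell and macrophage markers (17 of 26 higher, median 0.06, adjusted p = 0.0356, and 0.854 with an estimated correlation) included Cd9 at 0.36 ± 0.11 and Mpeg1 at 0.35 ± 0.12 (SE). Cholangiocyte and progenitor markers (8 of 14 higher, median 0.11, adjusted p = 0.0212, and 0.552 with an estimated correlation) were led by the keratins Krt8 at 0.63 ± 0.09 and Krt18 at 0.61 ± 0.09 (SE), which hepatocytes also make. Both rose over the list alone, whichever array was left out, and the other 12 members did not pass. T and NK cell markers were called lower (18 of 20, median -0.08, adjusted p = 0.00251, and 0.552 with an estimated correlation), with Nkg7 at -0.24 ± 0.09 and Ccl5 at -0.78 ± 0.29 (SE). Cell cycle genes (19 of 25 lower, median -0.05, adjusted p = 0.0276, and 0.552 with an estimated correlation) included Cdc20 at -0.22 ± 0.11 (SE). The T and NK cell call was kept whichever array was left out, and the mean of -0.12 was -0.23 with the brighter probe sets alone and -0.19 without the 2 arrays of lowest weight. Of the neutrophil, Kupffer cell, T and NK cell and cell cycle lists 0 genes passed over the list alone. On every array the means of the neutrophil and the T and NK cell lists lay under the olfactory receptor level, so dim genes enter these calls. The means of the cell cycle list, from 7.88 to 8.05, lay close to that level, so dim genes enter its call too. It was still called with the brighter probe sets alone (mean -0.084). Without Balb/c replicate 3 the calls of stellate (mean 0.081), neutrophil (0.070), Kupffer (-0.030) and cholangiocyte (0.098) lists were lost, against 0.16, 0.12, 0.094 and 0.13 with all arrays. Without Balb/cBy replicate 3 they were lost too, at means of 0.094, 0.10, 0.035 and 0.12. Without Balb/cBy replicate 1 those of neutrophil (0.12), cholangiocyte (0.13) and cell cycle (-0.036) lists were lost. The cell cycle list was also not called without Balb/c replicate 1 (-0.047), Balb/c replicate 2 (-0.056) or Balb/cBy replicate 3 (-0.063), and its mean was -0.10 in place of -0.067 without Balb/cBy replicate 2. The mean was 0.24 for stellate cells without Balb/c replicate 1, and for Kupffer cells 0.19 without Balb/c replicate 2 and 0.17 without Balb/cBy replicate 1. With the brighter probe sets alone neither neutrophil markers (0.038) nor Kupffer cell markers (0.11) were called, and the latter also not with renewed quantile normalization (0.055) or averaged probe sets (0.084). Without the 2 arrays of lowest weight the calls of neutrophil (0.064), Kupffer (0.046), cholangiocyte (0.095) and cell cycle (-0.066) lists were lost.

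Exocrine pancreas markers were lower in Balb/cBy (14 of 15, median -0.28, adjusted p = 2.25e-05, and 0.552 with an estimated correlation), and 0 passed over the list alone. The mean of the list was 7.79 on Balb/c replicate 3, where Ctrb1, a chymotrypsinogen, read 9.69 against 8.43 and 8.45 on the other Balb/c arrays. Without that array the mean difference was -0.091 in place of -0.25, with an adjusted p of 0.0474; over the settings run for lists the adjusted p ran from 4.17e-08 to 0.774, the latter by fry. The mean was -0.14, still called, without the 2 arrays of lowest weight. Cel, a pancreatic lipase, differed by -0.38 ± 0.11 (SE), with its Balb/cBy mean under the olfactory receptor level. On every array the mean of the whole list lay under that level too.

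**Figure D2:**
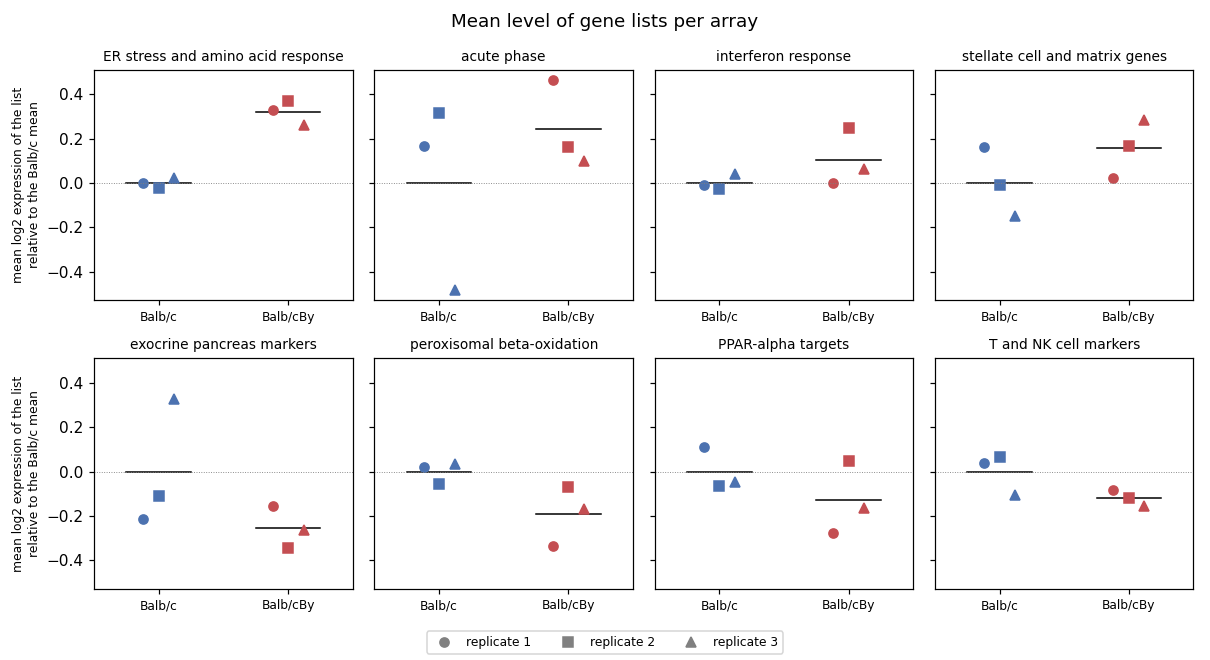
Mean log2 expression of 8 gene lists on each array (vertical axis, relative to the Balb/c mean of the list) by substrain. Symbols are replicates and lines group means; the ER stress list lies higher on each Balb/cBy array than on any Balb/c array, while Balb/c replicate 3 stands apart in the acute phase and exocrine pancreas lists.

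The B and plasma cell list was not called, while its members Ighm and Jchain were higher in Balb/cBy. Ighm, the heavy chain of IgM, read 9.52 ± 0.11 (SD, n = 3) in Balb/c and 11.11 ± 0.47 (SD, n = 3) in Balb/cBy, 3.02 times higher. Ighm and Jchain, the joining chain of secreted IgM and IgA (1.12 ± 0.28 SE), were the 2 of 11 members that rose over the list alone. The Balb/c mean of Jchain, 7.03, lay under the olfactory receptor level, so its difference is less certain. Ighm did so whichever array was left out, Jchain only without Balb/c replicate 3 (1.15) or Balb/cBy replicate 1 (1.48). The list's median was -0.05 and its mean 0.17, and camera did not call it (adjusted p = 0.979). Without Balb/cBy replicate 1, limma called 4 probe sets, all higher: those of Ighm at 1.86, of a pair of κ light chain variable segments at 1.97 and 1.49, and 1 of H2-Q5, a class I histocompatibility gene, at 1.93. The H2-Q5 probe set with the highest mean went the other way with all arrays, at -0.42 ± 0.13 (SE), and did not pass, so no direction is given for this gene. These belong to families of closely related genes, and probes shared between members were not checked.

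**Figure D3:**
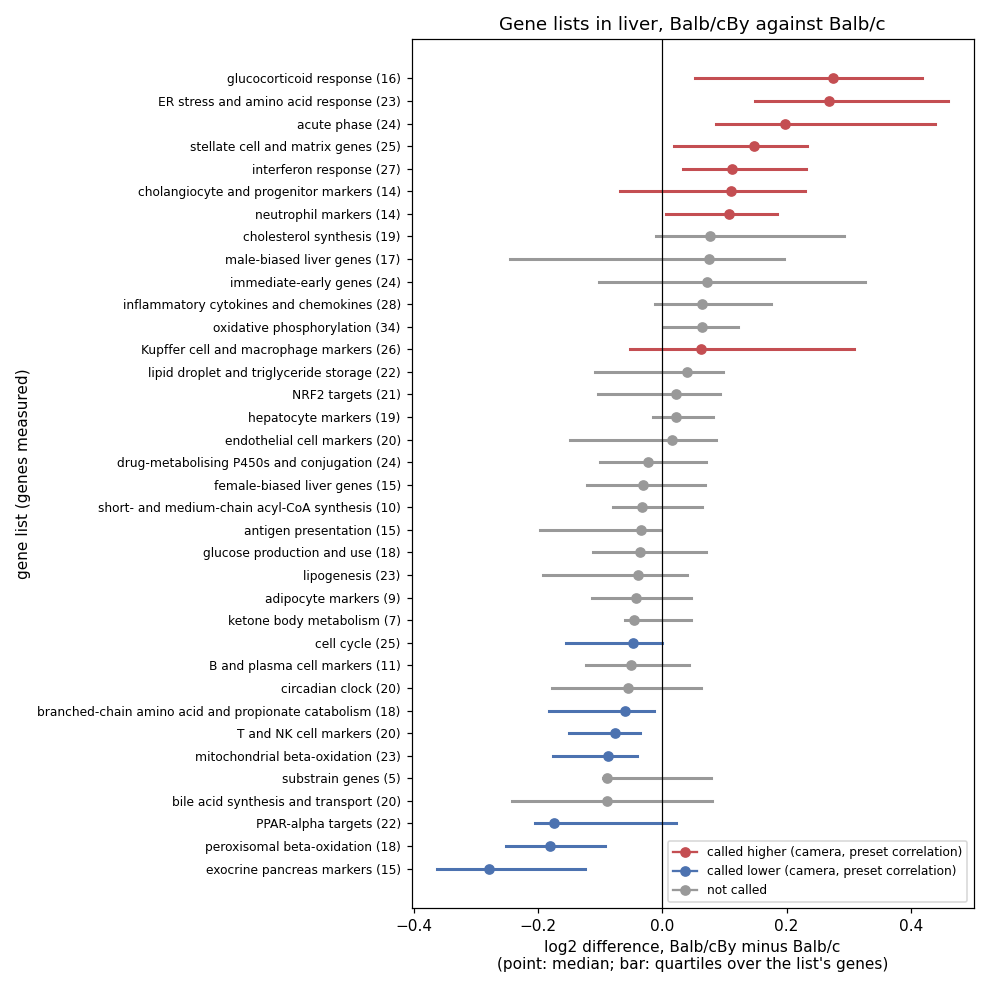
Median log2 difference, Balb/cBy minus Balb/c (horizontal axis), of the 36 gene lists tested, with bars from the lower to the upper quartile of the list's genes. Colours give camera's call at the preset correlation: 8 lists higher, 7 lower and the others not called.

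In all, camera called 15 of 36 lists at the preset correlation, 8 higher and 7 lower; with an estimated correlation it called 0, and fry called 1. Fry's mixed test, which asks whether genes of a list change in either direction, passed for cholangiocyte (adjusted p = 6.53e-05), ER stress (0.00712), substrain (0.0268) and B and plasma cell lists (0.0411). It can pass on few genes. Over the list alone only Krt8 and Krt18 passed among cholangiocyte genes, Acads among substrain genes, and Ighm and Jchain among B and plasma cell genes. Hepatocyte markers differed by a median of 0.02 (adjusted p = 0.213), endothelial markers by 0.02 (0.885) and adipocyte markers by -0.04 (0.885). Oxidative phosphorylation genes had a median of 0.06 (adjusted p = 0.115) and included Ndufs8 at 0.49 ± 0.20 (SE). Immediate-early genes had a median of 0.07 (adjusted p = 0.133), inflammatory cytokines and chemokines 0.06 (0.131), antigen presentation genes -0.03 (0.281) and NRF2 targets 0.02 (0.915). Glucose production and use had a median of -0.04 (adjusted p = 0.848), ketone body metabolism -0.05 (0.995) and the synthesis of short- and medium-chain acyl-CoA -0.03 (0.419). Drug-metabolising P450s and conjugating enzymes had a median of -0.02 (adjusted p = 0.995), male-biased liver genes 0.08 (0.387), female-biased liver genes -0.03 (0.995) and the circadian clock -0.05 (0.397). The 4 measured erythroid genes, too few for a test, had a median of 0.07. Leaving out 1 array gave calls to some of these lists. Oxidative phosphorylation was called higher without Balb/c replicate 1 (mean 0.13) or Balb/cBy replicate 1 (0.13), immediate-early genes without Balb/c replicate 2 (0.24) or Balb/cBy replicate 1 (0.30), cytokines without Balb/c replicate 2 (0.12) or Balb/cBy replicate 1 (0.11), and male-biased genes without Balb/c replicate 3 (0.17). Antigen presentation was called lower without Balb/c replicate 3 (-0.23) or Balb/cBy replicate 2 (-0.18), drug metabolism without Balb/c replicate 2 (-0.18), and endothelial (-0.073) and adipocyte markers (-0.12) without Balb/cBy replicate 3. Without the 2 arrays of lowest weight the circadian clock was called higher (0.18), against a mean of -0.044 with all arrays, as were hepatocyte markers (0.12), oxidative phosphorylation (0.11) and immediate-early genes (0.19). In 7 uncalled lists the median, the mean and camera's direction differed in sign: glucose use, endothelial, adipocyte, B and plasma cell, ketone body, drug metabolism and female-biased genes.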

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

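The alternative without both low-weight arrays was chosen after the data were seen; the others were planned. The count of 0 called probe sets held under every alternative except these: array weights called 31 (29 higher, 2 lower), single arrays left out 0 to 4 (0 to 4 higher, 0 lower), and both low-weight arrays left out 16 (13 higher, 3 lower). Of the 29 higher probe sets called with array weights, 15 were copies of Gm26504 with identical values. Acads kept its sign and stayed short of the threshold throughout, from -0.73 to -0.57 over all alternatives. Lists called by camera numbered 15, against 0 with an estimated correlation and 1 by fry; the other settings run for lists called 10 to 19. In the settings run for lists, the ER stress list lost its call only with an estimated correlation. The correlation estimated for this list was 0.031, little above the preset 0.01, while camera's unadjusted p went from 9.5e-13 to 0.0037. The lost call therefore cannot be put down to strongly correlated genes of this list. Array weights, the mean trend, no moderation, every probe set and the 1.5-fold minimum were run for single genes or their counts alone. Same-numbered arrays did not deviate together (r = -0.32, -0.20 and -0.23), and with the replicate block 0 probe sets and 16 lists were called, 15 of them among the main 15.

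Where a sign changed, the cause was not tested. Without both low-weight arrays, list means turned for mitochondrial β-oxidation (0.0096), acyl-CoA synthesis (0.055), bile acids (0.16, called), amino acid breakdown (0.030), P450s (0.079), female-biased genes (0.098), acute phase (-0.11), endothelium (0.027), clock (0.18, called), and gene values for Afp (-0.0030), Etfa (0.029), Bdh1 (0.096), Hlf (0.016). Renewed quantile normalization turned ketone bodies (-0.033), glucose (-0.025), lipid storage (-0.014), male-biased genes (-0.040), NRF2 targets (-0.035), adipocytes (-0.0063). The filter on brightness turned cytokines (-0.0063), adipocytes (-0.029), and median centring endothelium (0.0077). With single arrays left out, values spanned 0 for acyl-CoA synthesis (-0.10 to 0.041), ketone bodies (-0.077 to 0.084), lipogenesis (-0.18 to 0.039), cholesterol (-0.068 to 0.27), bile acids (-0.13 to 0.087), glucose (-0.056 to 0.14), lipid storage (-0.030 to 0.14), P450s (-0.18 to 0.029), male-biased genes (-0.098 to 0.17), female-biased genes (-0.11 to 0.10), NRF2 targets (-0.075 to 0.085), antigen presentation (-0.23 to 0.073), cytokines (-0.046 to 0.12), Kupffer cells (-0.030 to 0.19), endothelium (-0.073 to 0.084), adipocytes (-0.12 to 0.15), clock (-0.13 to 0.069), immediate-early genes (-0.058 to 0.30), Gpc3 (-0.16 to 0.0051) and Bdh1 (-0.28 to 0.0061). Of the lists named here, Kupffer cells, mitochondrial β-oxidation, amino acid breakdown and acute phase were called with all arrays. Among the 129 named genes other than Acads, 6 values changed sign in all. The filter on brightness left too few cholangiocyte and substrain genes for a test. Genes with means under the olfactory receptor level of 8.02 are limited by background, and their differences are the least certain.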

Other observations

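The tests of the pancreas list, of neighbouring genes and of the count of genes in other splits were chosen after the result was seen; the others were written down before.

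A probe set assigned to several genes of the H2-Q class I family, and therefore given no gene name, was among the clearest differences outside the main test: 10.30 in Balb/c and 8.88 in Balb/cBy, a difference of -1.41 ± 0.19 (SE). It was singled out after its values were seen, and it did not pass in the fit of every probe set. Another shared H2-Q probe set differed by -0.09 ± 0.17 (SE). Of 7 immunoglobulin probe sets above the olfactory receptor level, 6 were higher in Balb/cBy. That level was not required in each group: the probe set with the median difference lay under it in Balb/c and above it in Balb/cBy. A probe set can therefore be counted because it is high in Balb/cBy, so the count is no separate evidence of a direction.

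The higher level of ER stress genes in Balb/cBy was weighed against the time of sampling, the cell mix and the arrangement of the arrays. A score of clock genes averaged 0.73 in Balb/c and 0.77 in Balb/cBy, and with it as a covariate the list's difference was 0.32 ± 0.04 (SE), as without it; a score so balanced can hardly move a group difference, and the sampling time stays open. More antibody-secreting cells, which are rich in ER chaperones, may contribute: their markers above the olfactory receptor level, other than immunoglobulin and joining chains, differed by -0.041 ± 0.14 (SE), but these were just Sdc1 (9.69 in Balb/c), which hepatocytes also make, and Prdm1 (8.04), so this stays open. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05; the list's mean difference was 0.32 in the real split and 0.16 in the highest other. A difference between the substrains stays open too, as untested.

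The lower level of exocrine pancreas markers in Balb/cBy may come from pancreas tissue in the piece of Balb/c replicate 3. Without that array the mean difference was -0.091, smaller in size than -0.13, as set for this cause. It was also set that camera would no longer call the list without that array, which was not met. Camera still called the list there (adjusted p = 0.0474, range over the settings run for lists 4.17e-08 to 0.774) at the preset correlation, but not with all arrays and an estimated one (0.552), and the list means of the other 5 arrays overlapped between the groups. The abundant Ctrb1 read 9.69 on it and 8.19 to 8.45 on the other 5 arrays. Both this cause and a difference between the substrains stay open.

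Some genes with small p-values were neighbours. Among the 100 genes with the smallest p, 7 pairs lay within 5 genes of each other on GRCm38.p6, against a median of 2 in 10000 random sets of like expression (permutation p = 0.0188); the pairs seen prompted this test, so chance placement stays open. In all 7 pairs both genes were higher in Balb/cBy: Krt8 with Krt18, Btbd9 with Glo1, Neto1 with Rttn, Obp2a with Bmyc, Surf4 with Rexo4, Sult5a1 with Dpep1, and Dpagt1 with Hyou1. Of the 899 probe sets at an unadjusted p under 0.05, 621 were higher, so a shared upward direction is common among genes with small p. A candidate explanation for Btbd9 (0.66 ± 0.13 SE) and Glo1 (0.79 ± 0.19 SE) is a copy-number difference that covers both. The 4 genes above 8.02 within 3 positions of Glo1, Btbd9 among them, had a median of 0.044 and the 6 further ones -0.014. Their means reached down to 8.06 among the near genes and 8.04 among the further ones. Genes so close to background cannot show a copy-number difference, so these medians decide little. The predicted gene between Btbd9 and Glo1 lay under 8.02 and was not counted. Zfand3 (0.11 ± 0.11 SE, mean 11.17), on the Btbd9 side, lay below both genes, which argues against a region reaching it. On the other side of Glo1, 1700097N02Rik (-0.02 ± 0.09 SE) had a mean of 8.49, little above 8.02. A region reaching that way stays open, as does a narrow one.

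Other splits of the arrays bear on the counts. The real split called 0 probe sets by limma, a count that every split reaches, so this comparison decides nothing; the highest other called 1. Camera called 15 lists in the real split and 19 in the highest other, and 5 of the 10 splits, the real one included, called 15 or more; with 10 splits no share under 0.05 can be had. The split that set Balb/c replicate 1 and Balb/cBy replicates 2 and 3 against the rest gave 3156 probe sets at an unadjusted p under 0.05, against 899 in the real split, and called 0 past the adjusted threshold. It is the arrangement of the first principal component, which comes from the same arrays, so the count restates that component and adds no separate evidence.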
